A study of Homo sapiens with 20 samples.

How the data were processed

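Gene expression was measured in colon mucosa biopsies of 20 patients, with 1 Affymetrix human expression array of perfect-match probe sets per patient. The labels place 5 arrays with normal controls, 4 with quiescent ulcerative colitis and 11 with ulcerative colitis and neoplasia. The deposited values were log2 expression values of 54613 probe sets. Per the submitters' processing notes, the R package affy was used to make them, without a version. The method of background adjustment and of normalization was not given in the sources used here. The log2 scale was read from the deposited values themselves, which ran from 2.29 to 13.83, with array medians from 4.04 to 4.21. Signal over background could not be read from the values, so a change from or to a level near the array medians or below is a difference of measured values and not an exact fold. There were 0 missing values and 0 control probe sets in the table. The number of arrays limits the precision of every comparison.

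A single gene symbol was annotated for 40914 probe sets, several symbols for 864 and none for 12835. Entrez gene identifiers of 40858 of the 40914 were found in the RefSeq gene table of the human genome, and 0 symbols had to be updated; no coordinates were used. To protect the patients, 96 probe sets of XIST, TSIX and Y-linked genes, and 2 probe sets without a symbol that followed them, were left out of every test. Where a gene had more than 1 probe set, as 10535 of the 19730 genes tested did, the probe set with the highest mean over all 20 arrays stood for it.

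All 3 groups were fitted in 1 linear model per gene with limma version 3.58.1 in R version 4.3.3, without covariates, on the log2 values as deposited. The groups were compared by moderated two-sided tests, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all 19730 genes. Errors of log2 changes are standard errors of that fit, and errors of group levels are standard deviations (SD) over arrays. The patients of the groups are different people, so no pairing was used.

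The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each comparison, the 12 genes with the largest rise and the 12 with the largest fall among those that passed. Where fewer than 5 passed in a direction, it took the 5 with the smallest p in that direction. It also took, for each list, up to 4 members with the smallest p. HLA genes, immunoglobulin and T cell receptor segments outside the lists, and genes whose expression is set by common deletions or variants were left out of the named genes. Gene families described at the end were chosen after their values were seen.

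The 27 gene lists were colonocyte, goblet cell, enteroendocrine cell, crypt base and WNT target, Paneth-type antimicrobial, inflamed epithelium, gastric-type metaplasia, neutrophil and acute myeloid, monocyte and macrophage, T and NK cell, B cell and follicle, plasma cell, mast cell and eosinophil, fibroblast and matrix, smooth muscle, endothelium, enteric glia and neuron, proliferation, interferon response, immediate early and tissue handling, mitochondrial respiration, fatty acid, ketone and butyrate metabolism, drug metabolism and transport, DNA damage and mismatch repair, NF-kB and TNF signalling, distal colon, and proximal colon and ileum. Each list had at least 5 measured genes. Lists were tested against all other genes with camera of limma at a preset correlation of 0.01, adjusted over the 27 lists. The same lists were tested with the correlation estimated from the data, with fry, a rotation test of the list alone, and with an exact two-sided permutation test of each array's mean over the list.

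The sample descriptions carry running numbers in a low and a high range with a gap between them, and what the numbers stand for is not given in the sources used here. The low range held 3 controls, 3 quiescent arrays and 1 neoplasia array, and the high range held 2 controls, 1 quiescent array and 10 neoplasia arrays. The range was treated as a possible batch, as a term in the fit and by fits within each range. Where a range held 1 array of a group, that array was assumed to vary like the other groups.

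Other choices tried were all probe sets in place of 1 per gene, leaving out the 25 percent of genes with the lowest mean, quantile normalization, shifting arrays to 1 median, fits of only the groups compared, trended and robust moderation, array weights, the label number range as a covariate, the replicate numbers as a block, and leaving out each array in turn. A covariate for the ratio of 3' to 5' control probe sets was not run, since the table held 0 control probe sets. Leaving out the 2 arrays of lowest correlation and the fits within each label number range were chosen after seeing the data. Other splits of the arrays into groups of the same sizes were drawn 100 times per comparison with a fixed seed.

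The gene test was tested on simulated data with the real spreads of 19730 genes, of which 200 were changed. For quiescent colitis against controls it recovered 75% of the changes of log2 size 1 and 93% of those of size 2, with 12 false calls. For neoplasia against quiescent colitis it recovered 78% and 96%, with 7 false calls, and for neoplasia against controls 76% and 97%, with 3 false calls. In each comparison, 2 of 2 changed lists were recovered and 0 of 25 unchanged lists were called with camera. The simulated genes varied independently of each other. The simulation therefore does not test false calls by camera in lists whose genes vary together. Figures were drawn with matplotlib version 3.10.9 in Python version 3.11.15.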

Results

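Expression was profiled in colon mucosa biopsies of 20 patients, with 1 array per patient. Normal controls gave 5 arrays, patients with quiescent ulcerative colitis, the inactive phase of this inflammatory bowel disease, gave 4, and patients with ulcerative colitis and neoplasia gave 11. Per the series title, the mucosa sampled in the neoplasia group was not dysplastic and the lesions lay elsewhere. The labels used here state quiescence only for the second group, and give neither the segment of the colon sampled nor a grade of inflammation. Values are log2 expression levels of 19730 genes.

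The first principal component held 38.2% of the variance and ran from the controls (-70.6 to -37.3) to the neoplasia arrays (1.32 to 78.0). Quiescent replicates 1 to 3 lay between -42.5 and -29.8, and quiescent replicate 4 lay at 11.6, within the span of the neoplasia arrays. The median correlation of quiescent replicate 4 was 0.976 with the neoplasia arrays and 0.973 with the other quiescent arrays. Neoplasia replicate 12 lay at -102 on the second component, which held 18.2% of the variance, and had the lowest median correlation with the other arrays (0.882). Its mean over the smooth muscle list was 11.84, against 6.83 to 9.27 in the other 19 arrays. Control replicate 4 had the next lowest median correlation (0.900).

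**Figure D1:**
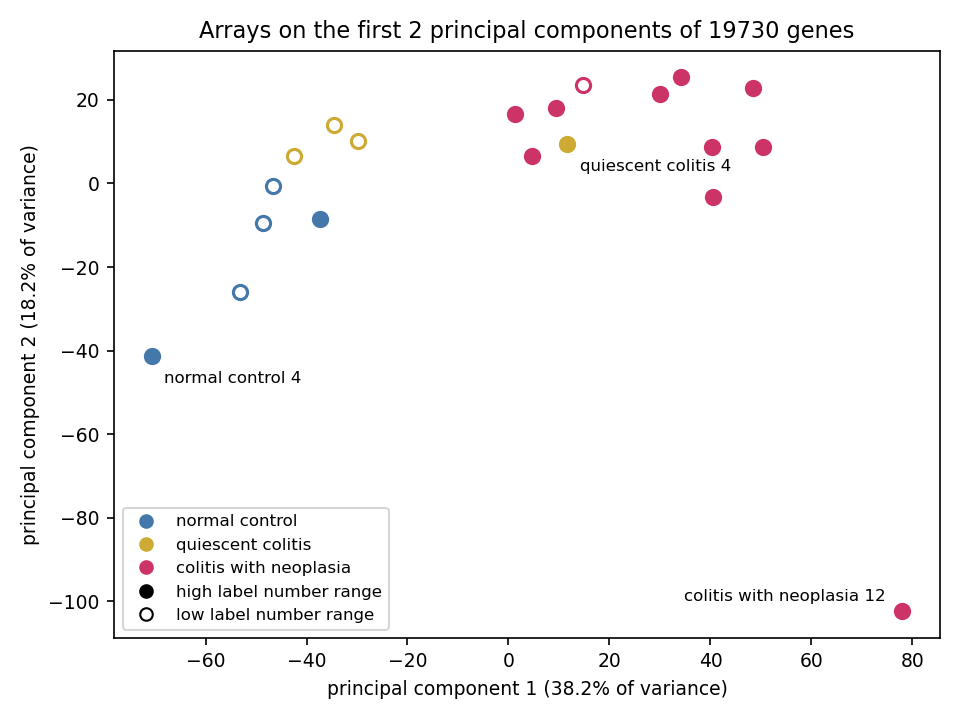
Each point is 1 array on the first 2 principal components of 19730 genes (unitless scores; axes give the percent of variance), coloured by group and filled where the sample label number lies in the high range. Quiescent replicate 4 lies at 11.6 on the first component and neoplasia replicate 12 at -102 on the second.

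Quiescent colitis was compared with normal mucosa to ask which genes differ outside the active phase of the disease. CCL11, a chemokine that attracts eosinophils, rose 10.6-fold, from 5.48 ± 0.51 (SD, n = 5) in controls to 8.88 ± 0.64 (SD, n = 4) in quiescent colitis (log2 change 3.40 ± 0.44 SE, adjusted p = 0.00359 by limma). TPM4, a tropomyosin of the actin cytoskeleton, rose 2.12-fold (log2 change 1.08 ± 0.16 SE, adjusted p = 0.0189), with 3 of its 5 probe sets in the same direction. Both genes were above the control mean in 4 of 4 quiescent arrays. Several other genes had large differences that did not pass. OLFM4, a glycoprotein of crypt base cells, differed by 4.31 ± 0.82 (log2, SE), SERPINB5, a serpin, by 3.64 ± 0.64, REG4, a secreted lectin, by 3.48 ± 0.71, and SPINK4, a goblet cell peptide, by 3.38 ± 0.63, each with adjusted p = 0.0591 and higher in 4 of 4 arrays. CLC, the Charcot-Leyden crystal protein of eosinophils, differed by 2.20 ± 0.54 (adjusted p = 0.111). The lower genes with the smallest p were LOC100129603 (-0.92), AGBL3 (-0.68), ASMT (-0.68), PRR23D2 (-0.77) and PROCA1 (-0.58), with adjusted p from 0.0591 to 0.0934.

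CCL11 and TPM4 were the 2 of 19730 genes that passed with limma, and 2830 genes had an unadjusted p under 0.05. CCL11 passed with each array left out in turn (adjusted p from 0.00154 to 0.0379) and did not pass within the low label number range alone (3 against 3 arrays, log2 change 3.35, adjusted p = 0.115) or the high range alone (1 against 2 arrays, 3.81, adjusted p = 0.150). TPM4 did not pass without quiescent replicate 3 (adjusted p = 0.125), quiescent replicate 4 (0.141) or control replicate 4 (0.0537), within the low range (log2 change 0.86, 0.243), after quantile normalization (0.147), with only these groups fitted (0.110) or with trended and robust moderation (0.0759). The count of genes was 4 without quiescent replicate 1, 1 without quiescent replicate 3 or 4, 5, 15, 48 and 85 without control replicates 1, 2, 3 and 5, and 59 without neoplasia replicate 12.

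Camera called 8 of the 27 lists, all higher in quiescent colitis, and 0 members of each passed over all genes. Fibroblast and matrix genes rose by a mean log2 change of 0.57 over 22 genes (adjusted p = 0.00199), endothelial genes by 0.49 over 19 (0.00862), and monocyte and macrophage genes by 0.38 over 16 (0.00862), each with adjusted p = 0.772 with an estimated correlation. NF-kB and TNF signalling genes rose by 0.59 over 18 genes (adjusted p = 0.00395), interferon response genes by 0.48 over 23 (0.00558), and DNA damage and mismatch repair genes by 0.32 over 21 (0.00558), again with adjusted p = 0.772 with an estimated correlation. Inflamed epithelium genes rose by 0.65 over 26 genes (adjusted p = 0.00925) and proliferation genes by 0.47 over 22 (0.0163), each with adjusted p = 0.925 with an estimated correlation. Adjusted over the list alone, 2 interferon response genes rose and 0 members of the other 7 lists passed. Members with small p that did not pass over all genes were the antiviral gene RSAD2 (1.59 ± 0.37, log2, SE), the monocyte chemokine CCL2 (2.41 ± 0.81), the matrix protein TNC (1.81 ± 0.61) and the calcium-binding protein S100P (2.14 ± 0.61). Of the 27 lists, 0 passed with an estimated correlation (0 at an unadjusted p under 0.05), 0 with fry (3) and 0 in the exact permutation test (8), in which the smallest p that 126 splits allow was 0.00794.

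Among the 19 lists not called were the distal colon list (mean log2 change -0.53, adjusted p = 0.0804), immediate early genes (0.47, 0.0804), the Paneth-type antimicrobial list (0.85, 0.139), goblet cell genes (0.36, 0.352) and colonocyte genes (-0.17, 0.474). The mean, median and test differed in sign for the crypt base, gastric-type, mast cell and eosinophil, proximal colon, fatty acid, and drug metabolism lists, none of them called. Of the 19 lists not called, that of the distal colon was called without quiescent replicate 1 (-0.72, adjusted p = 0.0133), control replicate 3 (-0.72, 0.0327), control replicate 4 (-0.61, 0.0261) or neoplasia replicate 12 (-0.53, 0.0272). Immediate early genes were called without quiescent replicate 3 (0.70, 0.00246), control replicate 2 (0.67, 0.0170), control replicate 5 (0.68, 0.0225) or neoplasia replicate 9 (0.47, 0.0423). The Paneth-type list was called without quiescent replicate 3 (1.09, 0.0373) or control replicate 4 (0.98, 0.0345), and mitochondrial respiration without quiescent replicate 1 (-0.13, 0.0343). Without quiescent replicate 4, 2 of the 8 calls were left. The means of the lost lists were then 0.21 for inflamed epithelium (adjusted p = 0.558), 0.23 for monocytes and macrophages (0.245), 0.35 for fibroblast and matrix (0.135), 0.24 for endothelium (0.356), 0.31 for interferon response (0.136) and 0.40 for NF-kB and TNF signalling (0.0773). The proliferation call was lost without quiescent replicate 3 (0.15, adjusted p = 0.499) or control replicate 1 (0.36, 0.122). In the low and the high label number range the means were 0.24 and 1.40 for fibroblast and matrix, 0.14 and 2.06 for inflamed epithelium, and 0.49 and 0.40 for proliferation.

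The comparison of the neoplasia group with quiescent colitis asked how colitis mucosa with a remote neoplastic lesion differs from colitis mucosa in the inactive phase. REG1A, a secreted lectin of the REG family, had the largest log2 change of the named genes, 5.14 ± 0.97 (SE, adjusted p = 0.016 by limma), from 4.17 ± 1.33 (SD, n = 4) to 9.30 ± 2.19 (SD, n = 11). Its quiescent level lay near the array medians, with quiescent replicate 4 above the other 3 arrays, and the change was 5.80 without that array, where it also passed. S100A8, a calcium-binding protein abundant in neutrophils, rose from 5.49 ± 1.39 (SD, n = 4) to 10.40 ± 1.50 (SD, n = 11; log2 change 4.91 ± 0.71 SE, adjusted p = 0.00989). REG3A rose by 4.80 with 1 of its 2 probe sets in that direction, the neutrophil chemokine CXCL8 by 4.14, REG1B by 4.12, the neutrophil Fc receptor FCGR3B by 4.04, the WNT inhibitor SFRP2 by 3.64 and the matrix metalloproteinase MMP3 by 3.06. BCL2A1, MGP, SERPINA3 and the cytokine IL1B rose by 2.81 to 2.97. The named rises lay above the quiescent mean in 10 or 11 of the 11 neoplasia arrays.

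Of the named genes that fell, TRPM6, a magnesium channel, had the largest change. It fell 7.20-fold (log2 change -2.85 ± 0.67 SE, adjusted p = 0.0368). SLC26A2, a sulfate transporter, fell 6.80-fold, from 11.69 ± 0.51 (SD, n = 4) to 8.92 ± 1.46 (SD, n = 11). TPH1, the enzyme of serotonin synthesis in enteroendocrine cells, fell by 2.38 on the log2 scale and did not overlap between the groups. EXPH5, CHP2, CDHR1 and VSIG10 had log2 changes of -2.43 to -2.09, and PIGZ, SELENBP1, MYO15B, SLITRK6 and SMIM5 of -1.95 to -1.75. All of these falls were seen in 11 of 11 neoplasia arrays against the quiescent mean.

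In all, 297 of 19730 genes passed with limma, 187 up and 110 down, among them 34 rises and 7 falls of at least 4-fold. The share of rises was 63.0% as deposited and 46.8% of 491 genes after quantile normalization. With the label number range as a term in the fit, 0 genes passed with limma (lowest adjusted p = 0.352, 1347 genes at an unadjusted p under 0.05), and all 297 kept their direction at a median size of 0.998 in place of 1.26. All 297 kept their direction within the low range too (1 against 3 arrays, at a median share of 0.95 of the change) and within the high range (10 against 1, at 0.485), though these arrays had entered the calls. In each range 1 of the groups was 1 array, so counts of genes passing within a range are weak evidence either way. In both ranges together, the count was 0 without quiescent replicate 1 (2497 genes at an unadjusted p under 0.05), replicate 2 (2079) or replicate 3 (2466). It was 926 without quiescent replicate 4, and 557, 136, 454, 176, 451, 479, 171, 175 and 721 without neoplasia replicates 1, 3, 4, 7, 8, 9, 10, 11 and 12. It was 157 when only these groups were fitted.

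Camera called 22 of the 27 lists, 14 up and 8 down. With an estimated correlation 0 passed (6 at an unadjusted p under 0.05), with fry 16, and in the exact permutation test 5, which were the neutrophil, monocyte and macrophage, mast cell and eosinophil, endothelium and Paneth-type lists. Neutrophil and acute myeloid genes rose by a mean log2 change of 2.09, from 4.76 ± 0.40 (SD, n = 4) to 6.85 ± 1.03 (SD, n = 11), with adjusted p = 0.106 with an estimated correlation. Of 21 members 8 rose, 0 fell and 13 did not pass, and 17 rose adjusted over the list alone. Besides S100A8, CXCL8 and FCGR3B they included MNDA, a myeloid nuclear antigen (2.81 ± 0.50, log2, SE). The monocyte and macrophage list rose by 0.65 (adjusted p = 0.106 with an estimated correlation), with 5 of 16 members up, 0 down and 11 not passing, and 9 up and 1 down adjusted over the list alone. Its members included the Fc receptor FCGR2A (1.58 ± 0.28) the mannose receptor MRC1 (1.37 ± 0.29) and the scavenger receptor CD163 (1.31 ± 0.29). Mast cell and eosinophil genes rose by 0.79 (adjusted p = 0.106 with an estimated correlation), with 3 of 12 up and 9 not passing, 4 up adjusted over the list alone, among them the mast cell protease CPA3 (1.92 ± 0.33) and CLC (2.33 ± 0.47).

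T and NK cell genes rose by 0.77 (adjusted p = 0.152 with an estimated correlation), with 2 of 21 up, the granzymes GZMB (1.97 ± 0.46) and GZMK (1.85 ± 0.46), and with 19 not passing and 6 up adjusted over the list alone. B cell and follicle genes rose by 1.07 (adjusted p = 0.152 with an estimated correlation) and plasma cell genes by 0.54 (0.390), with 0 of 16 members passing in each, and 7 and 0 up adjusted over the list alone. Stromal lists were higher too. Endothelial genes rose by 0.998 (adjusted p = 0.106 with an estimated correlation), with 6 of 19 up and 13 not passing, 13 up and 1 down adjusted over the list alone, among them the adhesion receptor SELP (1.65 ± 0.31) and the lymphatic marker LYVE1 (2.56 ± 0.53). Fibroblast and matrix genes rose by 0.81 (adjusted p = 0.152 with an estimated correlation), with 4 of 22 up and 18 not passing, 12 up adjusted over the list alone, among them the proteoglycan DCN (1.30 ± 0.28). Enteric glia and neuron genes rose by 0.53 (adjusted p = 0.322 with an estimated correlation), with 0 of 10 passing and 2 up adjusted over the list alone. Smooth muscle genes were not called (0.47, adjusted p = 0.104 by camera at the preset correlation and 0.673 with an estimated correlation). At the preset correlation they were called without quiescent replicate 4 (0.95, adjusted p = 0.00372) or neoplasia replicate 6 (0.62, 0.0278). Most of the smooth muscle change came from neoplasia replicate 12, at 11.84 against group means of 8.32 in neoplasia and 7.85 in quiescent colitis.

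Inflamed epithelium genes rose by 1.40 (adjusted p = 0.152 with an estimated correlation). Of 26 members 1 rose, the tryptophan-degrading enzyme IDO1 (2.76 ± 0.66), 25 did not pass, and 14 rose adjusted over the list alone. Paneth-type antimicrobial genes rose by 1.76 (adjusted p = 0.152 with an estimated correlation), with REG1A, REG1B and REG3A up and 8 of 11 not passing, REG4 (0.01) among them, and 3 up adjusted over the list alone. Among signalling lists, NF-kB and TNF rose by 0.61 (adjusted p = 0.183 with an estimated correlation; 1 of 18 up, the chemokine CCL4 at 2.26 ± 0.45, 5 up adjusted over the list alone). Interferon response rose by 0.58 (adjusted p = 0.152 with an estimated correlation), with 0 of 23 passing, and 10 up and 1 down adjusted over the list alone. Immediate early and tissue handling genes, which respond to handling of the biopsy, rose by 0.52 (adjusted p = 0.571 with an estimated correlation), with 0 of 18 passing either way.

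Lists of the absorptive and endocrine epithelium fell, and 20 general epithelial genes were at -0.91 in this comparison (-0.63 without neoplasia replicate 12). The difference from these genes was tested only for the colonocyte list. For the other epithelial lists, a lower share of epithelium was not told apart from a change within the cells. Colonocyte genes fell by 1.56, from 10.08 ± 0.34 (SD, n = 4) to 8.52 ± 1.20 (SD, n = 11), with adjusted p = 0.152 with an estimated correlation. SLC26A2 and TRPM6 fell, 19 of 21 members did not pass, and 11 fell adjusted over the list alone; the water channel AQP8 was at -3.84 ± 0.97 (adjusted p = 0.0501). Enteroendocrine genes fell by 1.15 (adjusted p = 0.152 with an estimated correlation), with TPH1 down, 12 of 13 not passing and 7 down adjusted over the list alone. Drug metabolism and transport fell by 0.90 (adjusted p = 0.152 with an estimated correlation), with the carnitine transporter SLC22A5 down (-1.70 ± 0.39), 20 of 21 not passing, and 8 down and 1 up adjusted over the list alone. Fatty acid, ketone and butyrate metabolism fell by 0.48 (adjusted p = 0.152 with an estimated correlation), with the enoyl-CoA hydratase ECHS1 (-0.60 ± 0.15) and the nuclear receptor PPARA (-1.05 ± 0.26) down, 19 of 21 not passing, and 8 down and 1 up adjusted over the list alone. The distal colon list fell by 0.81 (adjusted p = 0.152 with an estimated correlation; 0 of 9 passing, 2 down adjusted over the list alone) and goblet cell genes by 0.59 (adjusted p = 0.390 with an estimated correlation; 0 of 17 passing either way). Crypt base and WNT target genes fell by 0.32 (adjusted p = 0.189 with an estimated correlation), with the ephrin receptor EPHB3 (-1.02 ± 0.23) and PTPRO down, 16 of 18 not passing, and 4 down and 1 up adjusted over the list alone. Mitochondrial respiration fell by 0.13 (adjusted p = 0.571 with an estimated correlation; 0 of 25 passing, 1 down adjusted over the list alone). Not called were gastric-type metaplasia (0.12), DNA damage and mismatch repair (0.09), proximal colon and ileum (-0.27) and proliferation, whose mean was -0.05 and whose median was 0.01. The proximal colon and ileum list was called without quiescent replicate 1 (-0.30, adjusted p = 0.0474), quiescent replicate 3 (-0.31, 0.0339), neoplasia replicate 4 (-0.36, 0.0302) or neoplasia replicate 9 (-0.33, 0.0467). The proliferation mean was 0.27 without quiescent replicate 3 (adjusted p = 0.0791) and 0.15 without neoplasia replicate 12 (0.233).

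Within the low and the high label number range the mean changes were 3.46 and 1.37 for the neutrophil list, 0.78 and 0.22 for monocytes and macrophages, 1.0 and 0.28 for endothelium, 1.84 and 0.40 for Paneth-type genes, -0.68 and -1.19 for colonocytes, and -0.74 and -1.12 for enteroendocrine cells. With the range as a term they were 2.16, 0.51, 0.76, 1.22, -1.18 and -1.11. In the high range, where quiescent replicate 4 stood alone, inflamed epithelium genes were at -0.04, T and NK cell genes at -0.01, B cell genes at -0.01, immediate early genes at -0.13 and fibroblast and matrix genes at 0.12. Interferon response genes were there at 0.10, plasma cell genes at 0.024, NF-kB and TNF signalling genes at 0.021 and mitochondrial respiration genes at 0.016. The calls of 4 lists were lost with single arrays left out. For enteric glia and neuron this was so without quiescent replicate 1 or 2 or neoplasia replicate 3, 4, 12 or 13 (adjusted p from 0.0518 to 0.114). For immediate early genes it was so without quiescent replicate 2 or 3 or neoplasia replicate 3, 12 or 13 (0.0625 to 0.390), and for the distal colon list without quiescent replicate 1 (0.0928). The mitochondrial call was lost without quiescent replicate 1 or 3, control replicate 1, 3 or 4, or neoplasia replicate 1, 3, 6, 12 or 13 (0.0525 to 0.413).

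**Figure D2:**
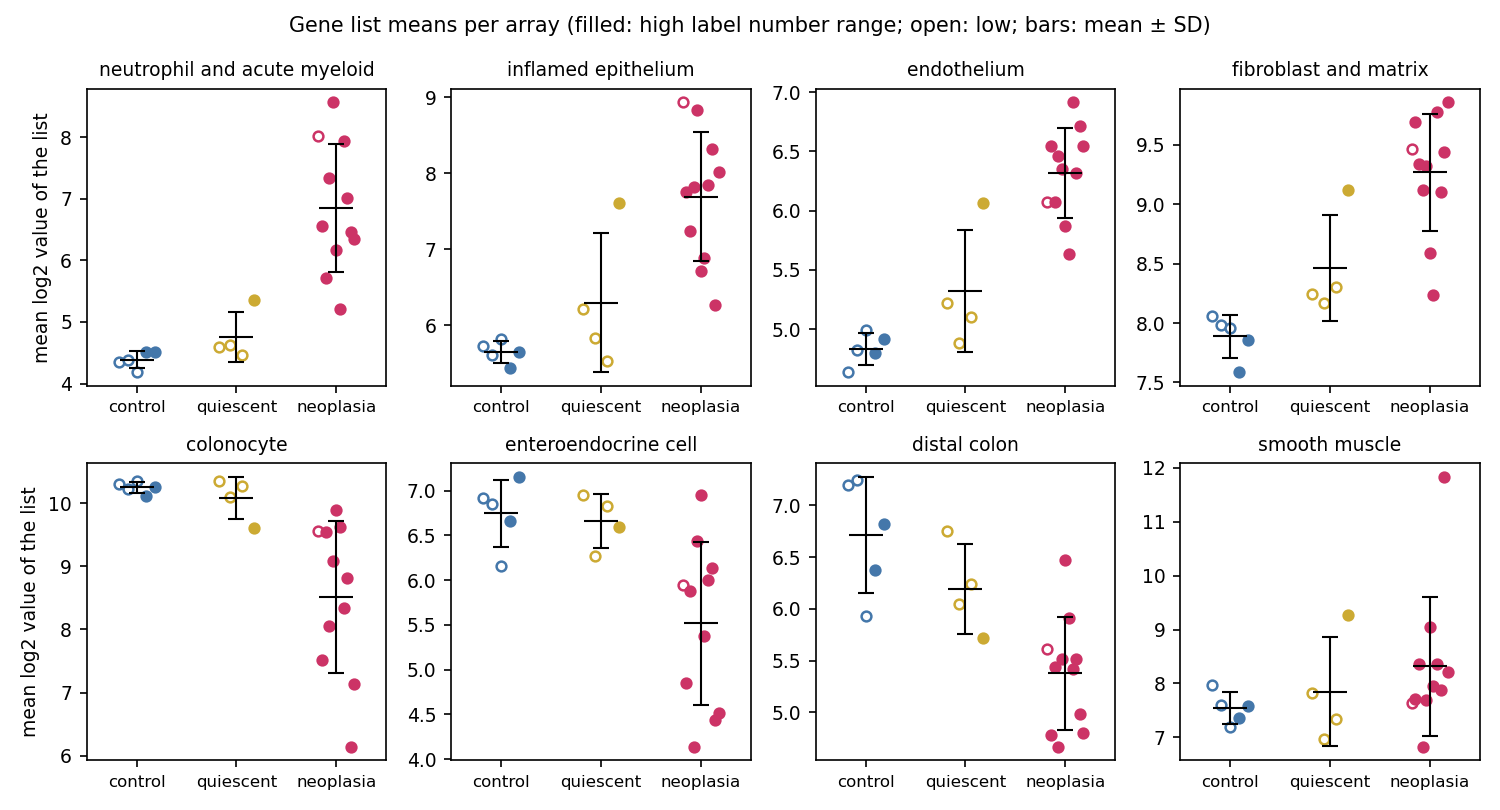
Mean log2 expression of 8 gene lists in each array (points; filled in the high label number range) with the group mean and SD (bars), for 5 controls, 4 quiescent arrays and 11 neoplasia arrays. The colonocyte list lies at 10.08 ± 0.34 in quiescent colitis and at 8.52 ± 1.20 in the neoplasia group.

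The neoplasia group was also compared with normal mucosa. CXCL8 rose from 4.52 ± 0.91 (SD, n = 5) to 10.66 ± 1.55 (SD, n = 11; log2 change 6.14 ± 0.70 SE, adjusted p = 1.54e-05 by limma). DEFA5, an antimicrobial peptide of Paneth cells, rose from 3.54 ± 0.40 (SD, n = 5), a level below every array median and not shown to lie above background, to 9.64 ± 2.28 (SD, n = 11; log2 change 6.11 ± 1.10 SE, adjusted p = 0.00057). S100A8 rose by 5.85, REG3A by 5.55 with 1 of its 2 probe sets in that direction, REG1A by 5.30, the secreted glycoprotein CHI3L1 by 5.25 and SERPINB5 by 4.90. FCGR3B, OLFM4, CLC, SFRP2 and the collagenase MMP1 rose by 4.30 to 4.59. Of the named falls that of AQP8, a water channel of surface colonocytes, was the largest, at 18.5-fold, from 10.35 ± 0.65 (SD, n = 5) to 6.15 ± 2.27 (SD, n = 11; log2 change -4.21 ± 0.90 SE, adjusted p = 0.00212). The tight junction gene CLDN8 fell 14.3-fold. The hormone SST fell 10.1-fold, TRPM6 10.1-fold, and SLC26A2, the guanylin genes GUCA2A and GUCA2B, and the granule protein CHGA by 8.33 to 8.50-fold. CHP2, CDHR1, EXPH5 and the metallothionein MT1M had log2 changes of -2.92 to -2.82. The named genes lay beyond the control mean in 11 of 11 neoplasia arrays.

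With limma 5215 genes passed, 3163 up and 2052 down, including 214 rises and 48 falls of at least 4-fold. The share of rises was 60.7% as deposited, 45.2% after quantile normalization and 71.2% with arrays shifted to 1 median. The count was 3694 with the label number range as a term, of which 3388 were among the 5215. It was 696 within the low range (1 against 3 arrays), where 96.6% of the 5215 kept their direction, and 2466 within the high range (10 against 2), where 5214 did.

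Camera called 22 of the 27 lists, 15 up and 7 down, fry 20 and the exact permutation test 19. With an estimated correlation 0 passed (5 at an unadjusted p under 0.05). Among immune lists, the neutrophil list rose by 2.46 (14 of 21 members up, 0 down, 15 up adjusted over the list alone), monocytes and macrophages by 1.02 (11 of 16 up, 0 down, 12), and interferon response by 1.06 (14 of 23 up, 0 down, 17), each with adjusted p = 0.198 with an estimated correlation. B cell and follicle genes rose by 1.39 (9 of 16 up, 12 adjusted over the list alone), and T and NK cell genes by 0.87 (10 of 21 up, 13), each with adjusted p = 0.234 with an estimated correlation. The B cell surface gene MS4A1 rose by 3.18 ± 0.73. Mast cell and eosinophil genes rose by 0.90 (4 of 12 up, 4 adjusted over the list alone; adjusted p = 0.216 with an estimated correlation). Plasma cell genes rose by 0.78 (5 of 16 up, 1 down, the same adjusted over the list alone; adjusted p = 0.413 with an estimated correlation) and did not pass the permutation test (adjusted p = 0.0921). The transcription factor XBP1 was among the plasma cell genes that rose (1.49 ± 0.32).

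Endothelial genes rose by 1.48 (14 of 19 up, 15 adjusted over the list alone), and fibroblast and matrix genes by 1.38 (16 of 22 up, 19), each with adjusted p = 0.198 with an estimated correlation. The thrombin receptor THBD rose by 3.42 ± 0.40 and the metalloproteinase inhibitor TIMP1 by 2.32 ± 0.28. Enteric glia and neuron genes rose by 0.86 (4 of 10 up, 4 adjusted over the list alone; adjusted p = 0.234 with an estimated correlation). Inflamed epithelium genes rose by 2.04 (18 of 26 up, 22 adjusted over the list alone), Paneth-type genes by 2.60 (8 of 11 up, 1 down, the same adjusted over the list alone), and NF-kB and TNF signalling by 1.20 (12 of 18 up, 13), each with adjusted p = 0.198 with an estimated correlation. The amino acid transporter SLC6A14 rose by 4.01 ± 0.62. DNA damage and mismatch repair genes rose by 0.41 (9 of 21 up, 1 down, 10 up and 1 down adjusted over the list alone; adjusted p = 0.234 with an estimated correlation), among them the DNA end-binding gene XRCC5 (0.74 ± 0.12) and the mismatch repair gene MSH6 (0.89 ± 0.16), with 2 of 4 MSH6 probe sets up. Immediate early genes rose by 0.995 (7 of 18 up, 7 adjusted over the list alone; adjusted p = 0.413 with an estimated correlation).

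Colonocyte genes fell by 1.73 (11 of 21 down, 0 up, 12 adjusted over the list alone), and enteroendocrine genes by 1.23 (8 of 13 down, 0 up, 8), each with adjusted p = 0.234 with an estimated correlation. The 20 general epithelial genes were at -0.89 against controls (-0.61 without neoplasia replicate 12). A lower share of epithelium may therefore be part of the falls of epithelial lists. The distal colon list fell by 1.34 (4 of 9 down, 4 adjusted over the list alone; adjusted p = 0.198 with an estimated correlation), among them the homeobox gene HOXB13 (-2.26 ± 0.52). Fatty acid, ketone and butyrate metabolism fell by 0.48 (11 of 21 down and 1 up, the same adjusted over the list alone; adjusted p = 0.234 with an estimated correlation), with the short-chain acyl-CoA dehydrogenase ACADS at -1.09 ± 0.18 and the acyl-CoA synthetase ACSL1 at 2.78 ± 0.41. Drug metabolism and transport fell by 0.80 (8 of 21 down and 1 up, the same adjusted over the list alone; adjusted p = 0.245 with an estimated correlation). Crypt base and WNT target genes fell by 0.27 (8 of 18 down and 2 up, the same adjusted over the list alone; adjusted p = 0.234 with an estimated correlation), with OLFM4 up by 4.58 and EPHB3 at -1.53 ± 0.21, and did not pass the permutation test (adjusted p = 0.158). Mitochondrial respiration fell by 0.19 (7 of 25 down and 3 up, the same adjusted over the list alone; adjusted p = 0.525 with an estimated correlation), and its call was lost without control replicate 1 (adjusted p = 0.0563), control replicate 5 (0.082) or neoplasia replicate 13 (0.072); it did not pass the permutation test (adjusted p = 0.0921). Not called were proliferation (0.42, 1 of 22 up), smooth muscle (0.78), gastric-type metaplasia (0.25, 1 of 13 down), goblet cell (-0.23) and proximal colon and ileum (-0.08, 2 of 18 up and 3 down). Of 17 goblet cell genes 3 rose, among them SPINK4 by 3.91, and 1 fell, with a median of -0.71 over the list. The proliferation list was called without control replicate 3 (0.54, adjusted p = 0.0286), neoplasia replicate 9 (0.46, 0.0438) or neoplasia replicate 12 (0.61, 0.000933), and the smooth muscle list without control replicate 1 (0.88, 0.0457) or neoplasia replicate 6 (0.93, 0.0304). Here too the smooth muscle change rests in part on neoplasia replicate 12, at 11.84 against a group mean of 8.32. In the low and the high label number range the means were 3.72 and 2.22 for the neutrophil list, 3.21 and 2.03 for inflamed epithelium, -0.73 and -1.77 for colonocytes and -1.18 and -1.25 for the distal colon list.

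**Figure D3:**
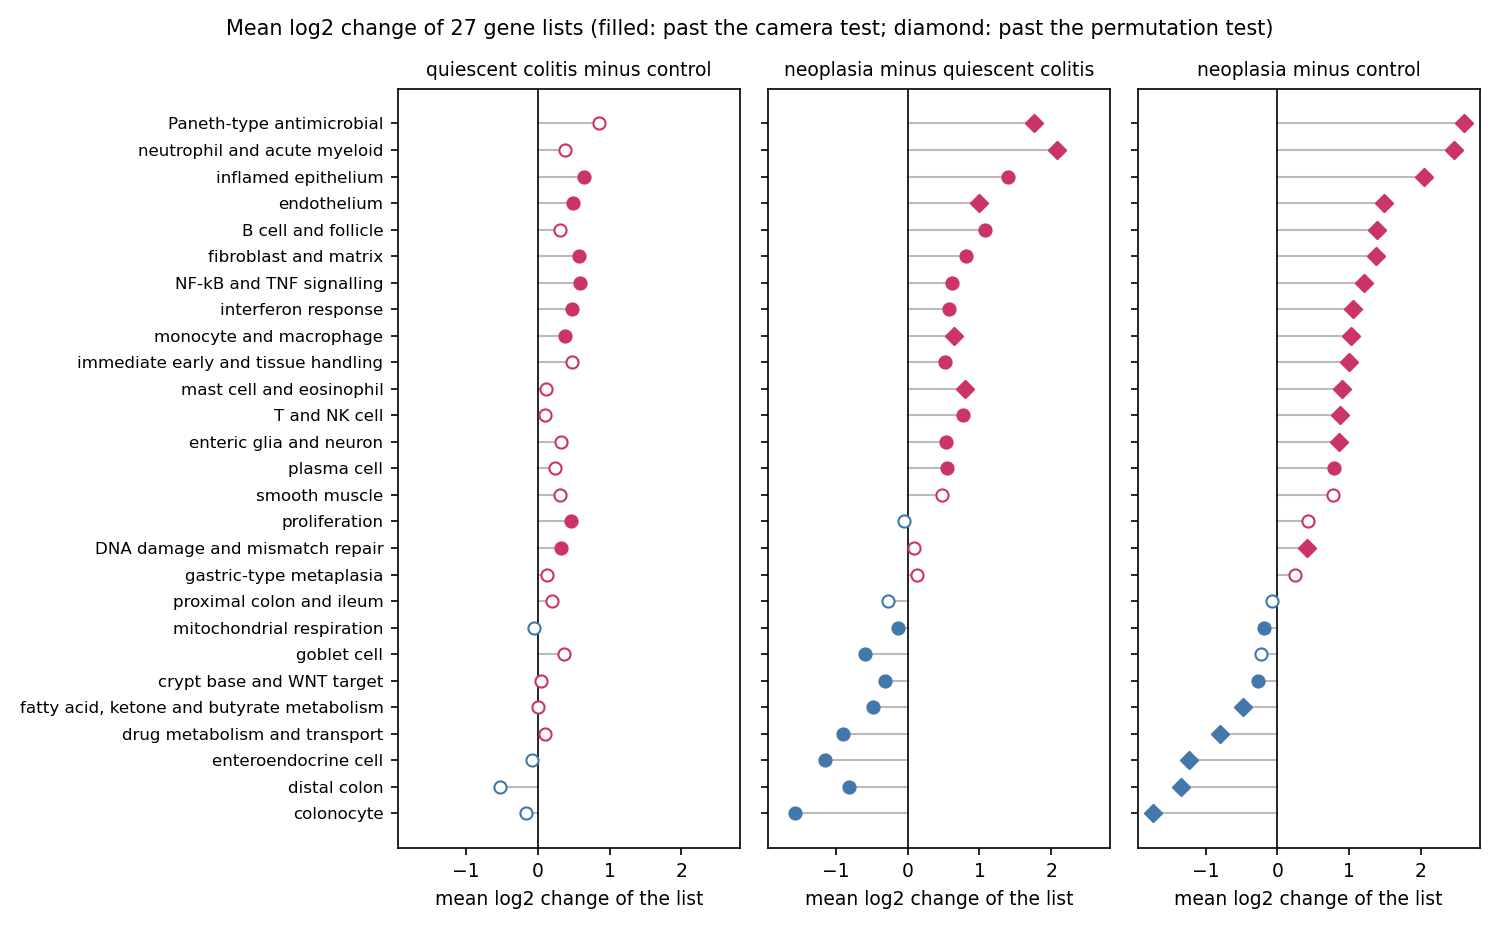
Mean log2 change of each of the 27 gene lists (points) in the 3 comparisons; red lies above 0 and blue below, filled points passed camera, and diamonds passed the exact permutation test. Camera called 8, 22 and 22 lists, and the permutation test 0, 5 and 19. The permutation counts come from 126, 1365 and 4368 splits, which allow smallest p of 0.00794, 0.00073 and 0.00023, so they are not alike in resolution.

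Both colitis groups were compared with the same controls. CCL11 lay at 9.37 ± 0.79 (SD, n = 11) in the neoplasia group and TPM4 at 8.65 ± 0.23, above the controls as in quiescent colitis. RSAD2 lay at 4.98 ± 0.32 (SD, n = 5) in controls, 6.58 ± 0.60 (SD, n = 4) in quiescent colitis and 5.59 ± 0.67 (SD, n = 11) in the neoplasia group. Across 19730 genes, which are not independent replicates, the changes of the colitis groups against the controls correlated with Pearson r = 0.70, and 78.1% had the same sign. In 100 simulations of unchanged groups that shared their controls, the median r was 0.56 (0.19 to 0.88). The median covariance was 0.0332 against the 0.153 observed. The simulations shuffled the deviations of all 20 arrays over the groups, so the simulated controls need not vary as the real ones did. With the controls split between the comparisons, the median r was 0.47 (0.34 to 0.57 over 20 splits) and the median covariance 0.119. Of the 297 genes that differed between neoplasia and quiescent colitis, 286 also passed against controls, all in the same direction (187 up, 99 down). These comparisons share the neoplasia arrays, so a shared direction is built in and was not tested further.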

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

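The tests of the label number range, of the share of epithelium, of smooth muscle and of a wrong label were chosen after the results were seen; the splits of the arrays and the test of the neutrophil level were not. Between neoplasia and quiescent colitis 297 genes passed, and 3 of 100 splits of the 15 colitis arrays, the real one included, gave as many, with 684 in the highest other split. Few splits gave as many genes, but another split gave more than the real split did, so chance is not excluded for that count. The split with 684 genes follows the label number range. It exchanges only quiescent replicate 4 and neoplasia replicate 1 and calls 185 of the 297. The range or another structure of the samples may therefore account for part of the count. With the range in the fit the call ended for all 297, at a median size of 0.998 in place of 1.26 and a median error of 0.311 in place of 0.278, so both a smaller size and a larger error contributed. High-range controls exceeded low-range controls over these genes by a median of only 0.111 (0.0327 to 0.235 over 6 pairs, SD 0.0918). This argues weakly against a range effect alike in every group as the whole cause. The high range held 2 controls, 1 of them control replicate 4, and the pairs reuse the same 5 arrays. Some of the genes, such as ITGAM at 3.73 in controls, lay below every array median there, where an effect may not show. The excess of quiescent replicate 4 (0.932) and of neoplasia replicate 1 (1.19) over the low-range quiescent arrays decides nothing, since those arrays had entered the choice of genes. Over genes called with the array itself left out, the excess was 0.885 for quiescent replicate 4 (926 genes). For neoplasia replicate 1 it was 0.755 (557 genes). The first is a difference within the quiescent group and the second within the low range. Each rests on 1 array, and the low-range quiescent arrays still entered those calls, so neither decides the cause. The level of neutrophil signal, from slopes within the neoplasia arrays, predicted a median share of 0.221 of the change (0.150 to 0.303 with 1 array left out) in the 289 genes outside that list. This argues only against a neutrophil effect of the same slope in both groups as the whole cause. The quiescent mean of the list (4.76) lay below every neoplasia array (5.21 to 8.56), where the slope is not known. The range and the neutrophil level stay open. So do the activity of inflammation and the segment sampled, which the labels do not give: the neutrophil list differed by 2.09 and the distal colon list by -0.81. A difference that goes with the remote lesion stays open as well.

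The colonocyte list was lower in the neoplasia group than in quiescent colitis by a mean log2 value of -1.56. A smooth muscle-rich biopsy was not the whole cause, since 0.848 of the fall was left without neoplasia replicate 12, and a lower share of epithelium could be part of it and cannot be told apart from a change within colonocytes. The colonocyte list fell further than 20 general epithelial genes, by a difference of -0.65 (exact permutation p = 0.0542, and -0.70 with p = 0.0390 without neoplasia replicate 12). The epithelial genes themselves were at -0.91 (exact permutation p = 0.101), and without neoplasia replicate 12 at -0.63 (p = 0.0140). Against controls, the difference was -0.84 (exact permutation p = 0.0119), and -0.89 without neoplasia replicate 12 (p = 0.0127), with the epithelial genes at -0.89 (p = 0.0506) and at -0.61 (p = 0.00633); in quiescent colitis against controls it was -0.19 (p = 0.00794, the smallest that 126 splits allow), with the epithelial genes at 0.02 (p = 0.921).

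Quiescent replicate 4 lay nearer to the neoplasia arrays than the other quiescent arrays did. Its high label number may account for this and cannot be told apart from the other explanations. The correlation of high-range controls with the neoplasia arrays minus that of low-range controls was -0.0273. Quiescent replicate 4 exceeded the other quiescent arrays by 0.0256. Control replicate 4 carried the control value, and without it 1 high-range control was left, at a difference of -7.2e-05. Neither control value showed the rise that a range effect alike in every group would give, but so few arrays cannot decide this. A wrong group label may explain it too and cannot be told apart from colitis that was more active in this patient. Its neutrophil list mean of 5.36 lay above the other quiescent arrays (4.46 to 4.63) and above that of 1 neoplasia array, near the low end of that group (5.21 to 8.56).

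For the other comparisons, 6 of 100 splits of the arrays of quiescent colitis and controls gave at least the 2 genes of the real split, with 99 in the highest other, so chance cannot be excluded for that count. For neoplasia against controls, 1 of 100 splits, the real one, gave 5215 genes, with 3 in the highest other, so chance can be excluded; the groups are unevenly spread over the label number ranges, and 3694 genes passed with the range in the fit.

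Single arrays lay apart from their group in 23 of 430 tested sets of values of 27 lists and 188 genes in controls and quiescent colitis, where chance sets apart about 1 in 20, and 11 of the 23 were of quiescent replicate 4; the neoplasia group, with 11 arrays, was not tested in this way. The values below are the gap to the nearest array over the range of the group. Quiescent replicate 4 was highest for the fibroblast and matrix list (0.863) and for XBP1 (0.925), GZMB (0.871), IL1B (0.906), REG1A (0.891), SFRP2 (0.836), AHR (0.917), DES (0.843) and TNFAIP6 (0.892), and lowest for TRPM6 (0.877) and CES2 (0.867). Quiescent replicate 2 was highest for the proximal colon and ileum list (0.838) and lowest for CHGA (0.869) and CD4 (0.851). Quiescent replicate 3 was highest for CDC20 (0.977), MCM2 (0.867) and TUBB3 (0.943), and quiescent replicate 1 for HOXD13 (0.930). Control replicate 4 was highest for the gastric-type metaplasia list (0.734) and for UQCRC1 (0.872), and lowest for the fatty acid, ketone and butyrate metabolism list (0.798) and for SLC26A2 (0.738) and AHR (0.869).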

How the results depend on the processing

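Leaving out the 2 arrays of lowest correlation and the fits within 1 label number range were chosen after seeing the data, and the other settings were planned. For quiescent colitis against controls, the 2 genes became 5 with all probe sets, 1 with quantile normalization, 31 with arrays shifted to 1 median, 1 with trended and robust moderation, 108 with array weights, 16 without the 2 arrays, 1 in the low range, 21 in the high range, and 1 to 85 with 1 array left out. Its 8 lists became 3 with dim genes left out, 13 in the high range, 0 with camera and an estimated correlation (0 at an unadjusted p under 0.05), 0 with fry (3), 0 by permutation (8), and 2 to 10 with 1 array left out. For neoplasia against quiescent colitis, the 297 genes became 482 with all probe sets, 468 with dim genes left out, 491 with quantile normalization, 157 with only these groups fitted, 3214 with array weights, 0 by limma with the label range in the fit (1347 at an unadjusted p under 0.05), 1035 without the 2 arrays, 0 in the high range (112), and 0 to 926 with 1 array left out, 0 by limma without quiescent replicate 1 (2497), 2 (2079) or 3 (2466). Its 22 lists became 9 in the high range, 0 with an estimated correlation (6), 5 by permutation, and 19 to 23 with 1 array left out. For neoplasia against controls, the 5215 genes became 11152 with all probe sets (of 54515), 696 in the low range, 2466 in the high range, and 3922 to 5952 with 1 array left out. Its 22 lists became 0 with an estimated correlation (5), and 21 to 23 with 1 array left out. The correlation of the colitis groups, 0.70, was 0.47 with split controls. In the high range, where quiescent replicate 4 stood alone and was assumed to vary like the other groups, these lists reversed between neoplasia and quiescent colitis, by the mean or by the direction of the test: inflamed epithelium (-0.036), T and NK cell (-0.0082), B cell and follicle (-0.0058), fibroblast and matrix (0.12), smooth muscle (-0.88), immediate early (-0.13), mitochondrial respiration (0.016) and NF-kB and TNF (0.021). In the low range the T and NK cell list reversed between quiescent colitis and controls (-0.19) and IGHA1 between neoplasia and controls (0.16). With 1 array left out, 1551 of 1620 list values kept direction and side of the threshold and 22 gained a call. The other 47 were weaker: they lost a call or, where there was none, turned direction without gaining one. For the genes named here, 2284 of 2560 kept both, 229 were weaker in that sense and 47 gained a call. These counts include leaving out arrays of the group outside the comparison, which cannot move the change itself, only the estimate of its spread. Under the other planned settings 809 of 972 list values and 858 of 1023 gene values kept both direction and side of the threshold. The cause was not tested. Fewer arrays enter the fits within a range.

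The replicate numbers, used as a block, belong to different patients, and arrays of the same number had a median residual correlation of -0.04 (-0.34 to 0.12, 10 pairs). With this block, 4 genes passed for quiescent colitis against controls. The counts were 1 for neoplasia against quiescent colitis and 356 for neoplasia against controls. Replicate numbers 6 to 13 occurred only in the neoplasia group and number 5 only in controls, so each of those arrays was absorbed by its own block term. The neoplasia comparisons therefore rested on neoplasia replicates 1, 3 and 4. Their lower counts reflect this loss of arrays as well as the degrees of freedom that the block uses up. With the block, the adjusted p by limma was 0.0884 for CCL11 and 0.220 for TPM4. The ratio of 3' to 5' control probe sets was not run. Signal over background could not be read from the values, so a low value is not shown to be absence.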

Other observations

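The 22 gene families from which these are taken were chosen and tested after the data had been seen. Genes of the proteasome, which degrades tagged proteins, were higher in the neoplasia group than in controls by a mean log2 value of 0.54 over 35 genes, with 24 up and 1 down, among them PSMA3 (1.36 ± 0.16 SE) and PSMC2 (0.93 ± 0.14), with adjusted p = 0.081 with an estimated correlation. Complement genes were higher by 0.95 over 20 genes (adjusted p = 0.081 with an estimated correlation), with 12 up and 1 down, among them the membrane regulator CD55 (3.22 ± 0.38) and the protease CFI (3.12 ± 0.41), and were higher than in quiescent colitis by 0.67 (adjusted p = 0.0341 with an estimated correlation). Serpins, a family of protease inhibitors, were higher than in quiescent colitis by 0.55 over 31 genes (adjusted p = 0.0235 with an estimated correlation), with 3 up, among them SERPINA3. RGS genes, regulators of G protein signalling, were higher by 0.58 over 20 genes (adjusted p = 0.0341 with an estimated correlation), with 2 up, RGS18 (2.03) and RGS5 (1.60).

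Against controls, chemokine ligands were higher by 1.43 over 36 genes (18 up, 3 down) and Toll-like receptors by 0.90 over 10 genes (5 up), among them TLR8 (2.16 ± 0.36) and TLR2 (1.93 ± 0.33), with adjusted p = 0.127 and 0.212 with an estimated correlation. Metallothioneins, which bind zinc and copper, were lower by a mean of -1.23 over 8 genes (6 down, adjusted p = 0.195 with an estimated correlation), among them MT1M (-2.82) and MT1E (-1.15), and in quiescent colitis by -0.91 with 0 members passing (adjusted p = 0.267 with an estimated correlation). HOX genes, which mark position along the gut, were lower by a mean of -0.38 over 29 genes (6 down, 1 up, adjusted p = 0.081 with an estimated correlation), with HOXB13 at -2.26, HOXB5 at -0.97 and HOXB2 at 0.89. Claudins of the tight junction were at a mean of -0.14 over 20 genes (4 up, 2 down, adjusted p = 0.958 with an estimated correlation), with CLDN1 at 1.74 and CLDN8 at -3.84. The means of these families kept their sign after quantile normalization and with arrays shifted to 1 median.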
